A study of Homo sapiens with 30 samples.

How the data were processed

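RNA of SW1783 astrocytoma cells was sequenced after 24 h of treatment in 30 libraries. Per the labels' protocols, the vehicle was 0.1% DMSO, RNA had an integrity number above 7, and libraries were made with the MGIEasy RNA Directional kit and read as 100 base pairs from both ends on an MGIseq instrument. The series description gives another DMSO share, and positive controls it mentions were not part of these samples. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to hg38 and counted per gene with RSEM 1.3.3. The deposited values are expected counts per gene, which are estimates: 24% of the nonzero values were not whole. The annotation release, the counting strand and any filter are not stated.

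The deposited table had 279 columns, of which 30 were used and 249 per-sample columns were left out. Expected counts were rounded. The table held 60675 genes, of which 34672 had a count in a used library, and 56558 gene IDs had a symbol and 57055 a position in GENCODE release 29 on GRCh38. Total counts ran from 22.57 M to 37.82 M. CPM in the text are computed from these counts with scaling by TMM, and log2 CPM with a prior count of 2.

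Genes were filtered by edgeR's filterByExpr with the groups, which kept 17839. A model with 1 mean per group was fitted to all 30 libraries in edgeR 4.0.16 on R 4.3.3 (TMM, estimateDisp, robust glmQLFit), so groups with 1 library borrow the spread of the others, and contrasts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Residual and prior degrees of freedom had a median of 33.7. Intervals are at 95%. Of 33 fixed gene lists with 664 genes, 607 of them tested, the 30 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The mean of 3 doses of an extract with 1 library each was compared with vehicle, and single libraries were described by values.

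Samples, groups, comparisons, tests, gene lists and all other settings except those named next were fixed before the data were examined. Not part of that plan were the test of the difference between the dose changes of both formulas and the count of genes shared over all comparisons with vehicle. The comparisons of 100 with 20 µg/mL, the removal of a trend of GC content and transcript length, the thinning to the lowest total, the comparison of single libraries at 500 and 20 µg/mL and the tests of explanations and splits were chosen after seeing the data. Genes were named by a fixed rule: a symbol and a mean log2 CPM of at least 1, and for each formula at 500 µg/mL against vehicle the 10 largest log2 fold changes each way among called genes whose libraries do not overlap, 5 each way in other comparisons, up to 4 members of a called list by smallest p, and a fixed set of marker genes. Genes of single libraries at 500 over 20 µg/mL were chosen after seeing the data.

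The fit was tested on simulated counts for Palmul-tang at 500 µg/mL against vehicle, with 200 of 17502 genes changed. The changed genes were drawn from those with a mean CPM of at least 5, so the recovery does not cover genes with lower counts. Of those at 1.25-fold 79.1% were recovered, and of those at 1.5-fold and 2-fold 100%, and 5 of 191 calls were false. With no simulated change, for Palmul-tang at 100 µg/mL against vehicle, 0 genes were called. Alternatives were size factors of DESeq2 in edgeR, the Wald test of DESeq2 1.42.0 (in which a local dispersion trend replaced the parametric one), no filter on low counts, a fit on the compared groups, a replicate block, counts thinned to the lowest total, a loess trend of GC content and length with span 0.3 removed, and each library left out.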

Results

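RNA was sequenced from SW1783 cells, a human astrocytoma line, after 24 h with herbal extracts of traditional Korean medicine or with their vehicle, 0.1% DMSO. The 30 libraries formed 16 groups. The vehicle group had 3 libraries, and the water extracts of Palmul-tang and Sibjeondaebo-tang had 3 libraries at each of 500, 100 and 20 µg/mL. The water extract of Samul-tang and the ethanol extracts of Poria Cocos and Atractylodis Rhizoma had 1 library at each of these doses. Palmul-tang contains the herbs of Samul-tang, Sibjeondaebo-tang contains those of Palmul-tang, and Poria is an herb of both larger formulas. Total counts per library ran from 22.57 M to 37.82 M, and genes of the mitochondrial chromosome took between 6.43% and 7.67% of them. Of 60675 genes in the table, 17839 passed the filter on low counts and were tested. No label says that libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

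The dose comparison within Palmul-tang asked which genes differed between 500 and 20 µg/mL. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716 in GRCh38), a chemokine that draws neutrophils, stood at 12 ± 0.978 CPM (SD, n = 3) at 20 µg/mL, 29.5 ± 0.394 at 100 and 106 ± 4.19 at 500, beside 10.9 ± 1.56 in vehicle. Its rise from 20 to 500 was 8.84-fold, with a log2 fold change of 3.14 ± 0.096 (SE) and an adjusted p of 2.64e-14. IL6 (chromosome 7, 22725884 to 22732002), an inflammatory cytokine, rose 2.94-fold from 6.6 ± 0.836 to 19.4 ± 1.01 CPM (adjusted p = 9.14e-16). IER3, an early response gene, rose 4.26-fold, SERPINB2, a plasminogen activator inhibitor, 3.04-fold, and IL1B, another inflammatory cytokine, 2.53-fold. The genes that fell most were SAMD11 (chromosome 1, 923928 to 944581), with a log2 fold change of -1.32 ± 0.052 (adjusted p = 9.21e-20), and ID2 and ID4, inhibitors of basic helix-loop-helix factors, with -1.22 ± 0.081 (adjusted p = 1.53e-13) and -1.20 ± 0.178 (adjusted p = 1.18e-05). The lincRNA LINC02593 fell by 1.10 and the homeobox gene DLX3 fell by 1.05 on the log2 scale.

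The fixed list of NF-kappa B and cytokine genes had 30 tested members, of which 28 rose, 0 fell and 2 were not called, and 29 rose and 1 fell adjusted over the list alone. Its median log2 fold change was 1.19 (camera, adjusted p = 9.78e-74, and adjusted p = 1.26e-08 with an estimated correlation). Among its members SOD2, the mitochondrial superoxide dismutase, rose 2.31-fold, the adhesion molecule ICAM1 2.41-fold, the monocyte chemokine CCL2 2.37-fold and TNFAIP3, a brake on NF-kappa B, 1.9-fold. Of 27 immediate early genes 10 rose, 1 fell and 16 were not called, with 12 up and 3 down adjusted over the list alone (camera, adjusted p = 5.05e-06, but adjusted p = 0.0958 with an estimated correlation). FOSL1 rose 1.44-fold and PHLDA1 1.29-fold. Against vehicle the median of this list had a mean of -0.172 at 20 µg/mL and -0.008 at 500, so it rose back to about the vehicle level. Of 7 aryl hydrocarbon receptor targets 3 rose, by either adjustment, and 4 were not called: ALDH1A3, a retinaldehyde dehydrogenase, rose 1.32-fold, TIPARP 1.23-fold and NQO1 1.16-fold (camera, adjusted p = 9.25e-06, and adjusted p = 0.0111 with an estimated correlation). Of 24 NRF2 targets, genes of the response to oxidants, 5 rose and 19 were not called, with 6 up and 1 down adjusted over the list alone, among them FTH1, the ferritin heavy chain (camera, adjusted p = 0.00539, but adjusted p = 0.0678 with an estimated correlation). Of 32 hypoxia and glycolysis genes 2 rose, 9 fell and 21 were not called, with 3 up and 13 down adjusted over the list alone; P4HA1 had a log2 fold change of -0.25 ± 0.035 and EGLN3, an oxygen-dependent prolyl hydroxylase, -0.70 ± 0.112 (camera, adjusted p = 9.25e-06, but adjusted p = 0.0678 with an estimated correlation). Of 29 extracellular matrix and TGF-beta targets 3 rose, 9 fell and 17 were not called, with 3 up and 10 down adjusted over the list alone; ACTA2, smooth muscle actin, fell by 0.45 on the log2 scale and CCN1, a matrix signal, rose 1.3-fold (camera, adjusted p = 0.0133, but adjusted p = 0.268 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, rose 1.72-fold (adjusted p = 5.8e-09). Camera called 14 of 30 lists in this comparison, and 2 of them, the cytokine list and the receptor targets, held with an estimated correlation. The share of all counts in noncoding genes was 3.074 ± 0.053% (SD, n = 3) at 20 µg/mL and 2.858 ± 0.053% at 500, and that of MALAT1 and NEAT1 0.168 ± 0.012% and 0.147 ± 0.007%.

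In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 946 genes between 500 and 20 µg/mL of Palmul-tang, 505 higher and 441 lower, and 55 of them differed by at least 2-fold. HMOX1, HMGCS1, MKI67, DDIT3, HSPA5, FKBP5 and CYP1A1, fixed in advance as markers of oxidant, sterol, growth, stress, steroid and xenobiotic responses, were not called; GFAP was too low to be tested. CDKN1A, a cell cycle inhibitor, had a log2 fold change of 0.22 ± 0.059 (adjusted p = 0.0183), a call lost without 500 replicate 1, 20 replicate 1 or 20 replicate 3 (adjusted p = 0.0837, 0.0888 and 0.136). Exons of IL6, IER3, ICAM1, SOD2, ID2, ACTA2, ALDH1A3, FTH1, PHLDA1, NQO1, TNFAIP3, TIPARP, P4HA1 and CDKN1A overlap annotated genes on the opposite strand, and those of SAMD11 overlap NOC2L over 378 bases. On the same strand, those of SERPINB2 overlap SERPINB10 over 547 bases, and those of SOD2 overlap a second entry named SOD2 over 845. The counting strand is not stated, so part of the counts of all these genes could belong to the partner. Of genes named in other comparisons this also holds for DUSP6, SLC7A11, VIPR1, HMGCS1, SERPINB3, PLK1, KRT18, UCA1, DDIT3, CALR, MX1, CCN2, LIF, MMP1, PTX3 and MALAT1, and on the same strand for IFITM10 and FOXO1.

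**Figure D1:**
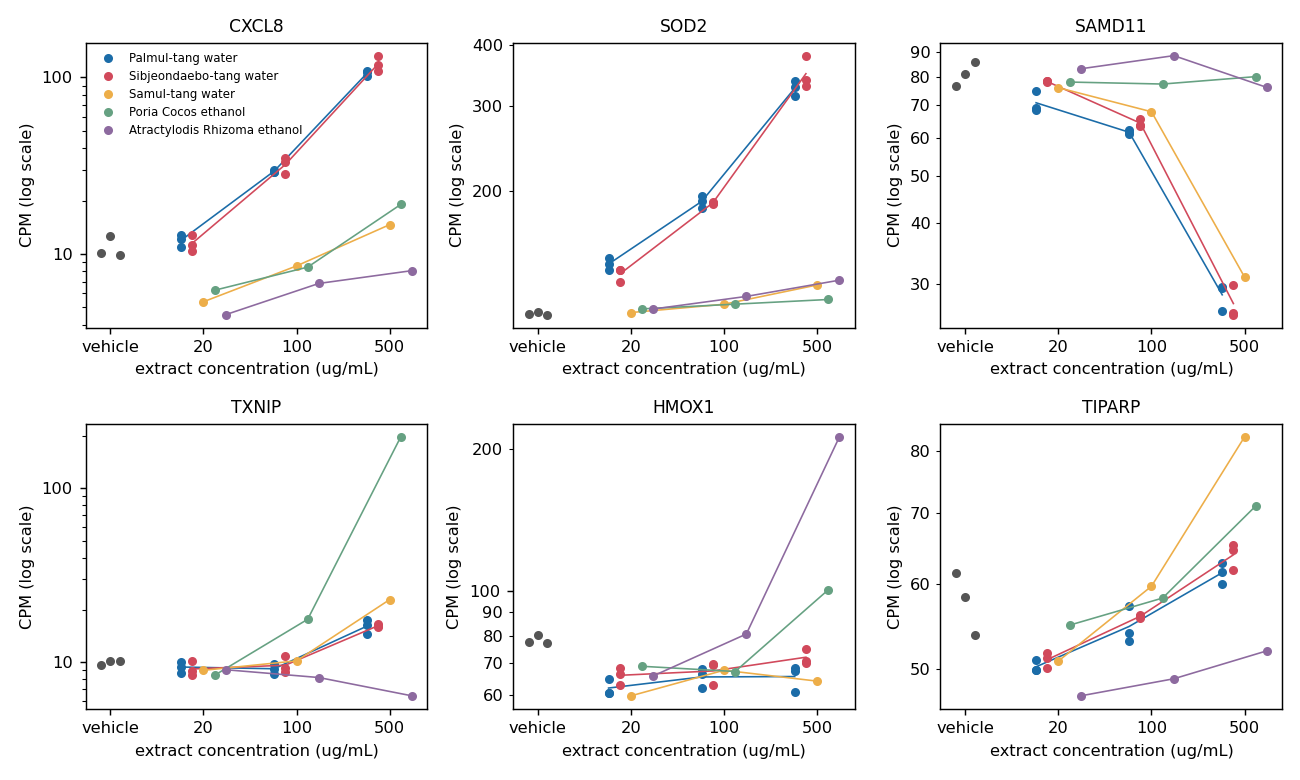
CPM on log axes of CXCL8, SOD2, SAMD11, TXNIP, HMOX1 and TIPARP against extract dose in µg/mL, with each point a library. CXCL8 reached a mean of 106 CPM in Palmul-tang and 120 CPM in Sibjeondaebo-tang at 500 µg/mL, and TXNIP stood at 198 CPM in the single Poria Cocos library at that dose.

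The same comparison within Sibjeondaebo-tang gave CXCL8 at 11.5 ± 1.22 CPM (SD, n = 3) at 20 µg/mL, 32.2 ± 3.39 at 100 and 120 ± 12.2 at 500, a rise of 10.4-fold (log2 fold change 3.38 ± 0.095, adjusted p = 6.33e-15). IL6 rose 3.95-fold, from 5.69 ± 0.623 to 22.5 ± 1.01 CPM, IER3 4.05-fold, SERPINB2 3.18-fold, IL1B 2.76-fold and SOD2 2.6-fold, from 135 ± 4.51 to 350 ± 27.6 CPM. DLX3 and SAMD11 fell by 1.52 each on the log2 scale, the estrogen-binding receptor gene GPER1 fell by 1.13, ID2 fell by 1.11 and ID4 fell by 1.07. TXNIP rose 1.78-fold, and FOXO1, a transcription factor that insulin restrains, fell by 0.57.

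Of the 30 NF-kappa B and cytokine genes tested, 27 rose, 0 fell and 3 were not called, with 29 up adjusted over the list alone, at a median log2 fold change of 1.06 (camera, adjusted p = 5.62e-74, and adjusted p = 1.23e-08 with an estimated correlation). Of 27 immediate early genes 10 rose, 1 fell and 16 were not called, with 12 up and 1 down adjusted over the list alone (camera, adjusted p = 0.0412 with an estimated correlation). DUSP6, a phosphatase of ERK, rose 1.42-fold. Against vehicle the median of this list had a mean of -0.173 at 20 µg/mL and 0.082 at 500. Of 7 aryl hydrocarbon receptor targets 4 rose and 3 were not called, with 6 up adjusted over the list alone, ALDH1A3 by 1.39-fold (adjusted p = 0.00227 with an estimated correlation). CYP1A1, the enzyme most used to read that receptor, was 1.8-fold higher (adjusted p = 0.0288), a call lost without 20 replicate 2, 20 replicate 3 or 500 replicate 3 (adjusted p = 0.202, 0.0937 and 0.162). Of 24 NRF2 targets 6 rose, 1 fell and 17 were not called, with 10 up and 1 down adjusted over the list alone (adjusted p = 0.00831 with an estimated correlation); FTH1 rose 1.23-fold and TXNRD1, thioredoxin reductase, 1.16-fold. Of 8 matrix metalloproteinases 4 rose and 4 were not called, with 4 up and 1 down adjusted over the list alone, MMP1 by 1.37-fold and MMP14 by 1.2-fold (adjusted p = 0.0239 with an estimated correlation). Of 9 astrocyte markers 4 fell and 5 were not called, with 1 up and 4 down adjusted over the list alone; ID3 fell by 0.88 and GLUL, glutamine synthetase, fell by 0.22 on the log2 scale (adjusted p = 0.0412 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 3 fell and 15 were not called, with 7 down adjusted over the list alone; HSPA5, the major chaperone of that compartment, had a log2 fold change of -0.14 ± 0.033 (adjusted p = 0.00499). Of 5 nuclear retained RNAs 3 fell and 2 were not called, with 4 down adjusted over the list alone; NEAT1, a nuclear noncoding RNA, fell by 0.38 on the log2 scale (adjusted p = 0.0205 for the list with an estimated correlation). The share of all counts in noncoding genes was 3.105 ± 0.065% (SD, n = 3) at 20 µg/mL, 2.815 ± 0.085% at 500 and 2.858 ± 0.061% in vehicle. Camera called 12 of 30 lists, and 9 held with an estimated correlation.

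The quasi-likelihood test of edgeR called 1113 genes between 500 and 20 µg/mL of Sibjeondaebo-tang, 615 higher and 498 lower, and 66 of them differed by at least 2-fold. The count was 636 when only the libraries of the compared groups were fitted. Replicate 3 at 500 µg/mL stood apart: the chi-square per gene was 8.144 and 7.421 between it and replicates 1 and 2, and 2.636 between those. Without it 1163 genes were called here and 5168 against vehicle, where 4472 were called with it. HMGCS1, of sterol synthesis, had a log2 fold change of -0.16 ± 0.042 (adjusted p = 0.0159), a call lost without 20 replicate 2 or 500 replicate 3 (adjusted p = 0.0873 and 0.0834). HMOX1, CDKN1A, MKI67, DDIT3 and FKBP5 were not called.

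**Figure D2:**
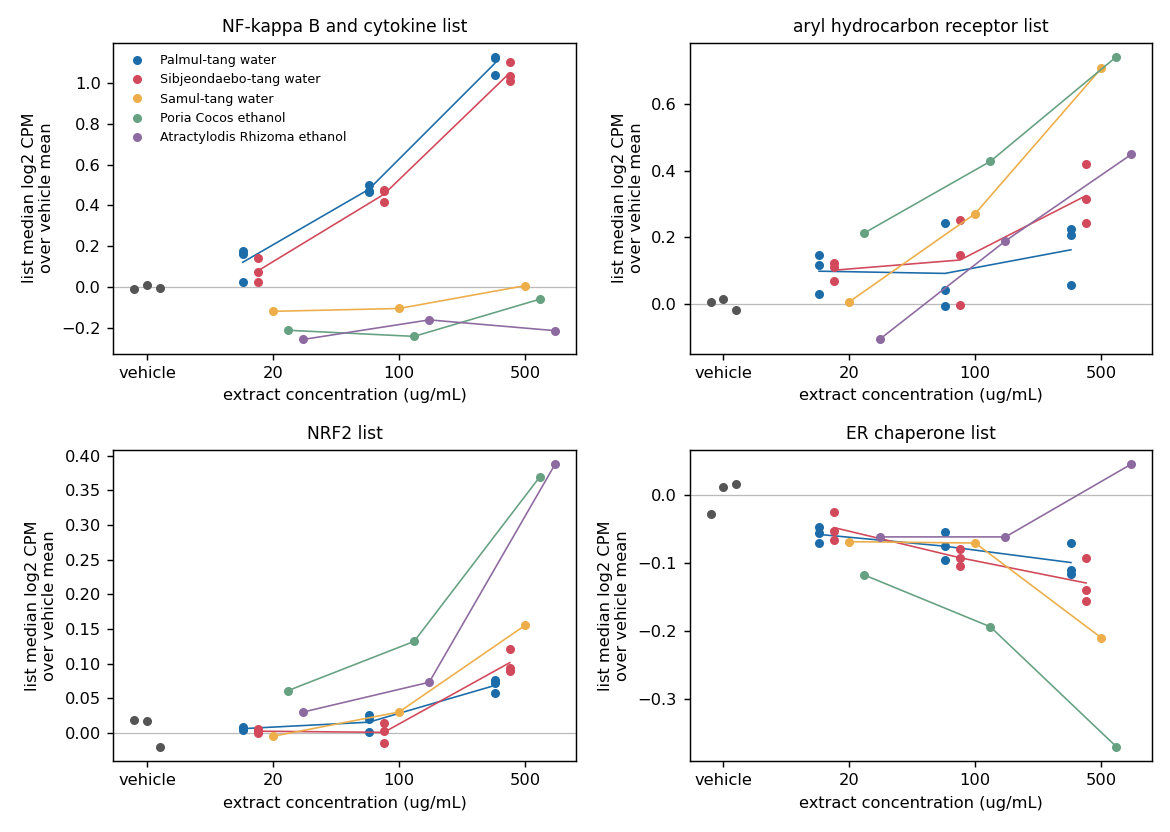
Median log2 change against vehicle of the fixed gene lists by dose in µg/mL for each extract, with lines joining the doses of an extract. The NF-kappa B and cytokine list reached a mean of 1.10 in Palmul-tang and 1.05 in Sibjeondaebo-tang at 500 µg/mL.

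The change from 20 to 500 µg/mL was set side by side in both formulas, whose libraries were separate. Of 946 genes called in Palmul-tang, 913 (96.5%) had the same sign in Sibjeondaebo-tang, among them CXCL8, IL6, SAMD11 and ID2. Called in both were 370 genes up, where independent lists would share 17.4, and 258 down, where they would share 12.3, and 0 genes were called in opposite directions. Across 10291 genes with a mean log2 CPM of at least 3, Pearson's r of the changes was 0.754 and Spearman's rho 0.578; over all 17839 genes they were 0.084 and 0.338, and genes are not independent replicates. A test of the difference between the changes called 0 genes in edgeR, with 716 at an unadjusted p under 0.05. That count lies under the share of 0.05 of all tested genes that would be expected with no difference.

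**Figure D3:**
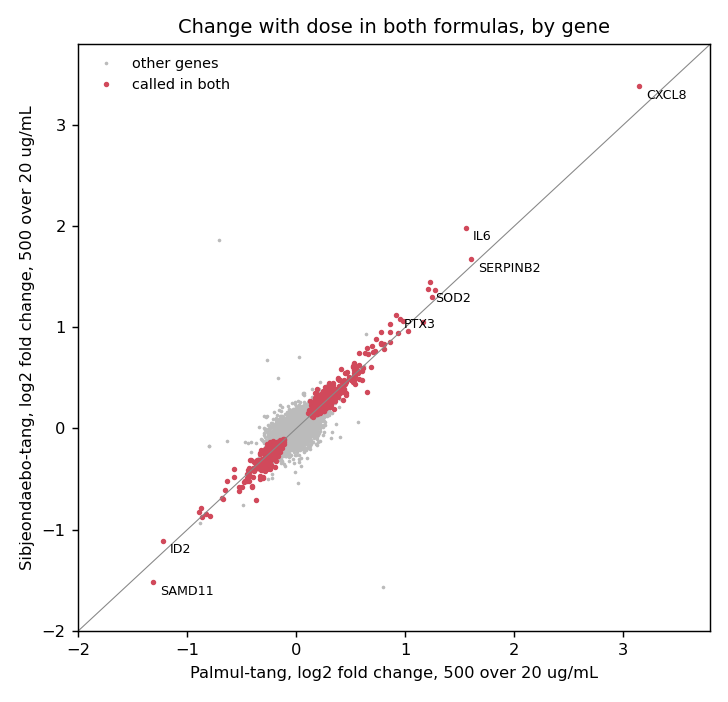
Log2 fold change from 20 to 500 µg/mL in Sibjeondaebo-tang against that in Palmul-tang, with each point a gene of mean log2 CPM of at least 3. CXCL8 lies farthest up in both (3.14 and 3.38), and SAMD11 lies at -1.32 and -1.52.

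Between 100 and 20 µg/mL, a comparison added after the data were seen, CXCL8 rose in Palmul-tang by 1.3 ± 0.106 (log2, SE, n = 3 per group, adjusted p = 2.26e-06) and in Sibjeondaebo-tang by 1.49 ± 0.103 (adjusted p = 1.81e-07). SERPINB2 rose by 0.63 and 0.75, and ICAM1 rose by 0.52 in Palmul-tang. IL6 rose by 0.67 ± 0.094 in Sibjeondaebo-tang (adjusted p = 6.66e-05), and SAMD11 there fell by 0.28. In Palmul-tang KRT18, a keratin of simple epithelia, had a log2 fold change of -0.19 ± 0.033 (adjusted p = 0.00247, and 0.0507 without 100 replicate 2). Of the 30 NF-kappa B and cytokine genes 15 rose in Palmul-tang and 16 in Sibjeondaebo-tang, 0 fell, and 26 and 22 rose adjusted over the list alone, at medians of 0.41 and 0.39 (adjusted p = 4.72e-08 and 6.55e-08 with an estimated correlation). In Palmul-tang IL6 had a log2 fold change of 0.45 ± 0.094 (adjusted p = 0.0274), a call lost without 100 replicate 2, 20 replicate 2, 100 replicate 3 or 20 replicate 3 (adjusted p = 0.308, 0.421, 0.16 and 0.167). The edgeR test called 29 genes in Palmul-tang, 26 higher and 3 lower, and 37 in Sibjeondaebo-tang, 33 higher and 4 lower. The first count was 15, 17, 19 and 17 without 100 replicate 1, 100 replicate 2, 20 replicate 2 or 20 replicate 3, and the second was 22, 24 and 17 without 20 replicate 1, 100 replicate 2 or 20 replicate 3. With no filter on low counts the counts were 51 and 63, and 56 genes were called in Sibjeondaebo-tang with a trend of GC content and transcript length removed.

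Sibjeondaebo-tang was compared with Palmul-tang at each dose. Doses are of whole extract, so the amount of each shared herb may differ too, and the comparison cannot isolate the added herbs. At 500 µg/mL CXCL8 stood at 120 ± 12.2 and 106 ± 4.19 CPM (SD, n = 3 each), SOD2 at 350 ± 27.6 and 326 ± 11.7, ICAM1 at 179 ± 4.57 and 177 ± 2.33, and SAMD11 at 27.3 ± 2.22 and 28.5 ± 1.79. IL6 differed by a log2 fold change of 0.21 ± 0.072 (adjusted p = 0.98), HMOX1 by 0.14 ± 0.047 (adjusted p = 0.98) and CYP1A1 by 0.43 ± 0.235 (adjusted p = 0.98). The edgeR test called 0 genes at 500, 100 and 20 µg/mL, with 863, 478 and 629 genes at an unadjusted p under 0.05. Each of these counts lies under the share of 0.05 of 17839 tested genes that would be expected with no difference. DESeq2 called 2 genes at 500 and 0 at the other doses. With no filter on low counts edgeR called 9, 7 and 3 genes, and it called 1 at 500 without Sibjeondaebo-tang replicate 3 and 2 at 100 without Sibjeondaebo-tang replicate 1. For genes with a mean log2 CPM of at least 3 the 95% interval of the difference had a median width of ± 0.103 at 500 µg/mL, and for 99.7% of them it lay within 1.5-fold. Camera called 10 of 30 lists at 500, 3 at 100 and 4 at 20, of which 0 held with an estimated correlation. At 500 the 7 aryl hydrocarbon receptor targets had a median of 0.07 (adjusted p = 0.109 with an estimated correlation) and the 6 metallothioneins and zinc exporters a median of -0.22 (adjusted p = 0.092 with an estimated correlation). At 100 the 31 interferon genes had a median of 0.15 (camera, adjusted p = 1.60e-07, but adjusted p = 0.602 with an estimated correlation).

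Against vehicle, both formulas at 500 µg/mL had the same leading rises. All vehicle libraries carry a code set (the first part of the sample code) that no treated library has. Comparisons with vehicle alone therefore cannot tell treatment from handling. CXCL8 rose by 3.29 ± 0.099 in Palmul-tang (log2, SE, n = 3 per group, adjusted p = 2.01e-14) and by 3.47 ± 0.099 in Sibjeondaebo-tang (adjusted p = 6.53e-15), and IL6 by 1.73 ± 0.089 and 1.95 ± 0.087. CLDN1, a tight junction protein, rose by 1.65 and 1.64, PTX3, a soluble pattern receptor, by 1.31 and 1.39, and NFKBIZ, a nuclear regulator of NF-kappa B, rose 2.45-fold in each. DLX3 had -1.61 and -1.66, SAMD11 -1.51 and -1.57, the long noncoding RNA UCA1 -1.10 and -1.19, and IFITM10 -1.13 and -1.05. ACTA2 fell by 0.85 and 0.82, and TXNIP rose by 0.69 and 0.70. SMAD6, an inhibitor of BMP signals, fell by 1.02 in Palmul-tang, and ANKRD1 and PGF, a growth factor of vessels, fell by 1.02 and 1.00 in Sibjeondaebo-tang. ZNG1F, FAM156B and RASA4B also ranked among the falls, but near-identical copies share their reads, so their values are uncertain.

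Of the 30 NF-kappa B and cytokine genes 29 rose and 1 was not called in Palmul-tang at 500 µg/mL, and all 30 rose in Sibjeondaebo-tang, with the same counts adjusted over the list alone (medians 1.10 and 1.05, adjusted p = 1.62e-06 and 7.71e-07 with an estimated correlation). Of 77 ribosomal protein genes 2 rose and 40 fell in Palmul-tang and 2 rose and 37 fell in Sibjeondaebo-tang, with 42 down adjusted over the list alone in each (medians -0.15 and -0.12; camera, adjusted p = 2.41e-08 and 1.27e-06, but adjusted p = 0.19 and 0.278 with an estimated correlation). Of 28 mitosis genes 13 and 14 fell and 3 and 2 rose, with PLK1, a mitotic kinase, at -0.34 and -0.36. Of these genes 14 fell in each adjusted over the list alone (camera, adjusted p = 0.00459 and 5.41e-05, but adjusted p = 0.205 and 0.0862 with an estimated correlation). Of 25 genes of cholesterol synthesis and uptake 9 and 7 fell and 0 rose, and 9 fell in each adjusted over the list alone; HMGCS1, of sterol synthesis, fell by 0.21 and 0.22 (camera, adjusted p = 0.00114 and 0.00177, but adjusted p = 0.0973 and 0.0624 with an estimated correlation). The median of the cholesterol list had a mean of -0.101 and -0.096 at 500 µg/mL, and already -0.048 and -0.052 at 20. MKI67, a proliferation marker, fell by 0.22 and 0.18, and the stress factor DDIT3 fell by 0.44 and 0.45. Neither MKI67 nor DDIT3 was called between 500 and 20 µg/mL of either formula. HMOX1, heme oxygenase, fell by 0.26 in Palmul-tang and had -0.12 ± 0.047 in Sibjeondaebo-tang (adjusted p = 0.0518). CDKN1A, FKBP5, HSPA5 and CYP1A1 were not called in either. Camera called 12 and 14 of 30 lists, of which 1 and 3 held with an estimated correlation; the others that held in Sibjeondaebo-tang were the aryl hydrocarbon receptor targets (adjusted p = 0.0193) and the endoplasmic reticulum chaperones (adjusted p = 0.0307).

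Many genes moved against vehicle at every dose. In Palmul-tang at 20 µg/mL NEAT1 (chromosome 11, 65422774 to 65445540), the scaffold RNA of paraspeckles, stood at 551 ± 14.1 CPM (SD, n = 3) against 298 ± 12.1 in vehicle, and RPL14, a ribosomal protein gene, at 338 ± 5.31 against 434 ± 4.49. In Sibjeondaebo-tang at that dose NEAT1 rose by 1.00 ± 0.05 (adjusted p = 3.15e-12). RPL14 lay between 315 and 351 CPM in every treated group. MALAT1 and NEAT1 together took 0.116 ± 0.004% of all counts in vehicle (SD, n = 3), 0.168 ± 0.012% and 0.171 ± 0.004% at 20 µg/mL of Palmul-tang and Sibjeondaebo-tang, and 0.147 ± 0.007% and 0.15 ± 0.013% at 500. Ribosomal protein genes took 3.926 ± 0.098% in vehicle. In Palmul-tang and Sibjeondaebo-tang they took 3.846 ± 0.109% and 3.739 ± 0.064% at 20 µg/mL, and 3.671 ± 0.046% and 3.75 ± 0.061% at 500. Over the 9 comparisons with vehicle 737 genes were higher in all and 1174 lower in all. The comparisons use the same 3 vehicle libraries, so part of this may come from them, and no value for unchanged groups was computed for all 9 together. Among the shared rises NEAT1 had a mean log2 fold change of 0.79 (0.44 to 1.00), MARK2, a microtubule kinase, 1.04 and ZSCAN31 0.75; among the shared falls CCN2, a matrix growth factor, had -0.72, the forkhead factor FOXD1 -0.70, ANGPTL4, a lipase inhibitor, -0.68 and SNAI1, a factor of epithelial transitions, -0.58. The pseudogenes HERC2P3, HERC2P2, AHSA2P, NSUN5P1, RPS2P46, MORF4L1P1 and RPL14P1 were also among them, with values that reads from their parent genes make uncertain. On the first principal component, with 8.1% of the variance, vehicle libraries lay apart from all treated libraries, and the second held 7.2%. With a trend of GC content and transcript length removed, 56.4% of the 4243 genes called at 20 µg/mL of Palmul-tang stayed called in the same direction.

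**Figure D4:**
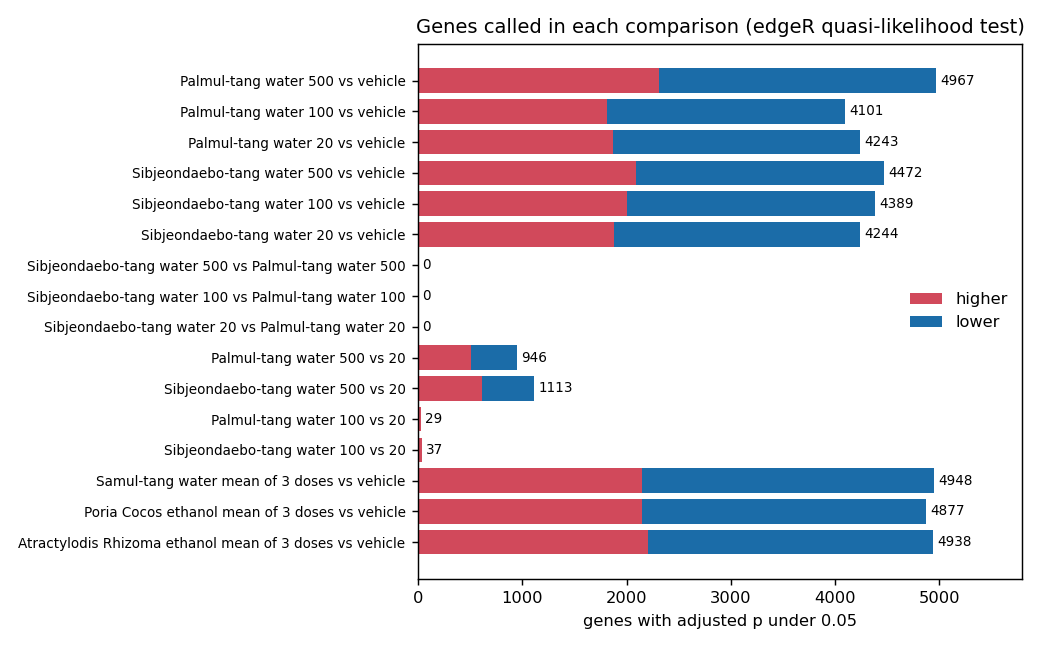
Number of genes with an adjusted p under 0.05 in each comparison, with bars split into genes higher and lower. Against vehicle the bars run from 4101 to 4967 genes, and between both formulas at the same dose they are at 0.

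For the genes called in both formulas at 500 µg/mL against vehicle, 1673 were shared among the rises, CXCL8 and SOD2 among them, and 2006 among the falls, DLX3 and SAMD11 among them. Independent lists would share 270.9 and 354.5. In 20 simulations all libraries, vehicle included, were drawn from a common mean per gene, with a shared vehicle group. There the mean overlap was 0.2 and the highest 2. The simulations hold no shift of the vehicle libraries, so they cannot address handling of these apart from the treated ones. The covariance of the log2 fold changes was 0.0339, beside 0.00206 in the simulations, and the correlation across genes, which are not independent replicates, was 0.947 beside 0.512. The 3 vehicle libraries were too few to split, so part of the excess may come from the shared controls. The edgeR test called 4967 genes in Palmul-tang at 500 µg/mL, 2309 higher and 2658 lower, and 4472 in Sibjeondaebo-tang, 2093 higher and 2379 lower, of which 452 and 410 differed by at least 1.5-fold.

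At 100 µg/mL against vehicle CXCL8 rose by 1.45 ± 0.11 (log2, SE, n = 3 per group, adjusted p = 4.36e-08) in Palmul-tang and by 1.58 ± 0.108 (adjusted p = 1.15e-08) in Sibjeondaebo-tang, and IL6 by 0.63 ± 0.098 and 0.63 ± 0.097. SOD2 rose 1.7-fold and 1.69-fold, and ICAM1 1.54-fold and 1.45-fold. ANGPTL4 had a log2 fold change of -0.80 in Palmul-tang and -0.82 in Sibjeondaebo-tang. Of the 30 NF-kappa B and cytokine genes 18 rose, 3 fell and 9 were not called in each formula, with 22 and 21 up and 3 down adjusted over the list alone (medians 0.54 and 0.48, adjusted p = 0.000682 and 0.00109 with an estimated correlation). In Sibjeondaebo-tang MX1, an antiviral GTPase, had 1.39 ± 0.387 (adjusted p = 0.0163), a call lost without vehicle replicate 1 or 100 replicate 2 (1.35 and 0.56, adjusted p = 0.057 and 0.0754). Of 31 interferon genes 18 rose there, 0 fell and 13 were not called, with 22 up adjusted over the list alone (camera, adjusted p = 3.32e-06, but adjusted p = 0.445 with an estimated correlation), and 8 of the 18 stayed called without 100 replicate 2. Called by edgeR were 4101 genes in Palmul-tang and 4389 in Sibjeondaebo-tang.

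At 20 µg/mL against vehicle the cytokine genes went both ways. In Palmul-tang SOD2 rose 1.26-fold, while the monocyte chemokine CCL2 fell by 0.46, PTGS2, the inducible cyclooxygenase, fell by 0.63 and LIF fell by 0.65 on the log2 scale; in Sibjeondaebo-tang CCL2 fell by 0.45, PTGS2 fell by 0.59 and LIF fell by 0.74. IL6 had 0.18 ± 0.102 (adjusted p = 0.224) and -0.04 ± 0.104 (adjusted p = 0.832). The early response gene FOSL1 fell by 0.47 and 0.45. Of the 30 NF-kappa B and cytokine genes 7 rose, 5 fell and 18 were not called in Palmul-tang and 8 rose, 6 fell and 16 were not called in Sibjeondaebo-tang, with the same counts adjusted over the list alone (camera, adjusted p = 0.342 and 0.615). Of 5 nuclear retained RNAs all 5 rose in each formula, by either adjustment (camera, adjusted p = 0.000173 and 1.12e-05; medians 0.30 and 0.37, adjusted p = 0.0637 and 0.0324 with an estimated correlation). The edgeR test called 4243 genes in Palmul-tang, 1868 higher and 2375 lower, and 4244 in Sibjeondaebo-tang, 1880 higher and 2364 lower.

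For the extracts with 1 library per dose, the mean over 3 doses was compared with vehicle. Its SE and p come from the spread within the groups that had 3 libraries and leave out the spread between the doses of an extract, so they hold for the mean of these libraries only. In Samul-tang the receptor gene VIPR1 rose by 1.12 ± 0.121 (log2, SE, 1 library at each of 3 doses against 3, adjusted p = 1.26e-08), the early response gene EGR1 by 0.81 ± 0.069 (adjusted p = 2.22e-10) and NQO1, a quinone reductase, by 0.44 ± 0.031 (adjusted p = 4.03e-12), and CCL2 fell by 0.57. Of 7 aryl hydrocarbon receptor targets 4 rose, 0 fell and 3 were not called, with 5 up adjusted over the list alone (adjusted p = 0.0365 with an estimated correlation). In the libraries at 20, 100 and 500 µg/mL the median of this list was 0.006, 0.271 and 0.707 against vehicle, so its mean rests largely on the 500 µg/mL library, without which EGR1 had 0.54 (adjusted p = 4.19e-06) and TIPARP -0.07 (adjusted p = 0.333). TXNIP had 0.36 ± 0.084 (adjusted p = 0.00143), but -0.06 without the 500 µg/mL library (adjusted p = 0.701). In all, 4948 genes were called by edgeR, 2148 higher and 2800 lower.

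In Poria Cocos the squamous serpin SERPINB3 rose by 1.01 ± 0.134 (adjusted p = 7.01e-07), TXNIP by 1.63 ± 0.08 (adjusted p = 2.86e-16) and NQO1 by 0.56 ± 0.031 (adjusted p = 7.32e-15). Without the 500 µg/mL library TXNIP had 0.29 and NQO1 0.37, and TXNIP had 2.57 without the 20 µg/mL library, all still called. The TXNIP libraries at 20, 100 and 500 µg/mL lay at -0.25, 0.82 and 4.3 against vehicle, a spread that the SE leaves out. CBS, an enzyme of transsulfuration, fell by 1.12 and HERPUD1, of the unfolded protein response, fell by 0.81 on the log2 scale. CBS had -0.39 without the 20 µg/mL library, still called, so its mean rests largely on that library. Of 18 endoplasmic reticulum chaperones 11 fell, 0 rose and 7 were not called, with 1 up and 13 down adjusted over the list alone (median -0.23, adjusted p = 0.00439 with an estimated correlation), with MANF at -0.39 and CALR at -0.32. The chaperone list had medians of -0.118, -0.194 and -0.37 against vehicle in the libraries at 20, 100 and 500 µg/mL. Of 24 NRF2 targets 13 rose, 1 fell and 10 were not called, with 14 up and 1 down adjusted over the list alone (adjusted p = 0.0122 with an estimated correlation), and the medians of this list were 0.061, 0.132 and 0.37 at 20, 100 and 500 µg/mL, so the mean rests largely on 1 library. EIF3CL ranked first among the falls, but its reads are shared with a near-identical copy, so its value is uncertain. In all, 4877 genes were called by edgeR, 2150 higher and 2727 lower.

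In Atractylodis Rhizoma the zinc finger gene ZSCAN31 rose by 1.04 ± 0.081 (adjusted p = 1.24e-11) and the cystine transporter SLC7A11 by 0.56 ± 0.043 (adjusted p = 1.09e-11), but SLC7A11 had 0.28 without the 500 µg/mL library, still called. CCL2 fell by 0.97, the keratin-associated gene KRTAP2-3 fell by 1.24, LIF fell by 0.81 and PTGS2 fell by 0.75 on the log2 scale. CCL2, LIF and PTGS2 also fell against vehicle in both formulas at 20 µg/mL, so their falls were not particular to this extract. Of 24 NRF2 targets 15 rose, 1 fell and 8 were not called, with 16 up and 2 down adjusted over the list alone (median 0.18, adjusted p = 0.00753 with an estimated correlation). In the libraries at 20, 100 and 500 µg/mL the median of the NRF2 list was 0.03, 0.073 and 0.388 against vehicle, so its mean over doses rests on the 500 µg/mL library. Of the 30 NF-kappa B and cytokine genes 1 rose, 14 fell and 15 were not called, with 2 up and 15 down adjusted over the list alone (median -0.29; camera, adjusted p = 0.0121 with an estimated correlation). From the single library at 20 to that at 500 µg/mL this list instead rose, with a median of 0.128 and 23 members higher. Of 28 mitosis genes 1 rose, 16 fell and 11 were not called, with 1 up and 17 down adjusted over the list alone, with PLK1 at -0.41 and AURKA at -0.30 (adjusted p = 0.048 with an estimated correlation). HMOX1 had 0.41 ± 0.047 (adjusted p = 3.72e-08), but -0.11 without the 500 µg/mL library (adjusted p = 0.144). The HMOX1 libraries at 20, 100 and 500 µg/mL lay at -0.26, 0.04 and 1.44 against vehicle, a spread that the SE leaves out. In all, 4938 genes were called by edgeR, 2204 higher and 2734 lower.

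Between single libraries at 500 and 20 µg/mL, which have no replicate check, genes were chosen in each extract after the data were seen, by size of change and a steady order over the doses. In Samul-tang CXCL8 stood at 5.38, 8.58 and 14.7 CPM at 20, 100 and 500 µg/mL, IGFBP1, a binding protein of insulin-like growth factors, at 18.4, 24.7 and 47.2, SAMD11 at 76.1, 67.9 and 31, and ID2 at 22.3, 19.3 and 11.3. The vehicle mean of CXCL8 lay between its values at 100 and 500 µg/mL, so much of its rise started below vehicle. In Poria Cocos TXNIP stood at 8.42, 17.7 and 198 CPM beside 10 ± 0.309 in vehicle. In Atractylodis Rhizoma HMOX1 stood at 65.8, 80.8 and 213 CPM beside 78.5 ± 1.57 in vehicle, PLIN2, a coat protein of lipid droplets, at 48.9, 55.8 and 96.6, and the keratin KRT18 at 164, 143 and 95.4. The median log2 change of the aryl hydrocarbon receptor targets was 0.657 in Samul-tang, 0.529 in Poria Cocos and 0.234 in Atractylodis Rhizoma, and that of the NRF2 targets was 0.162, 0.323 and 0.374. That of the ATF4 targets was -0.058, -0.119 and 0.367, and that of the endoplasmic reticulum chaperones -0.199, -0.271 and 0.104. Past 1.5-fold lay 30 genes up and 23 down in Samul-tang, 23 and 20 in Poria Cocos and 13 and 7 in Atractylodis Rhizoma, of 10291, where pairs of replicates had between 5 and 25.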

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

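The tests of growth with dose, of dependence on 1 library, of an ingredient shared with Samul-tang and of other splits of the libraries were chosen only after the result was seen.

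Between Sibjeondaebo-tang and Palmul-tang at the same dose camera called lists of genes as different between both formulas, while edgeR called 0 single genes (863, 478 and 629 at an unadjusted p under 0.05 at 500, 100 and 20 µg/mL, and 2, 0 and 0 in DESeq2). At 500 µg/mL the adjusted p was 0.00676 for the aryl hydrocarbon receptor targets, 0.0354 for DNA replication, 0.0212 for endoplasmic reticulum chaperones, 0.00983 for hypoxia and glycolysis, 0.00371 for metallothioneins and zinc export, 0.00777 for mitochondrially encoded genes, 0.048 for mitosis, 0.019 for NRF2 targets, 0.00983 for nuclear oxidative phosphorylation and 0.0257 for ribosomal proteins. At 100 µg/mL it was 0.0316 for hypoxia and glycolysis, 1.60e-07 for the interferon response and 0.00822 for mitochondrially encoded genes. At 20 µg/mL it was 0.0213 for nuclear oxidative phosphorylation, 0.0499 for nuclear retained RNA, 7.99e-07 for ribosomal proteins and 0.0213 for ribosome biogenesis and MYC targets. With an estimated correlation 0 of these calls held. The gene counts at an unadjusted p under 0.05 lie under the share of 0.05 of 17839 tested genes expected with no difference.

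At 20 µg/mL 4243 genes were called between Palmul-tang and vehicle, RPL14 and NEAT1 among them. A trend of GC content and transcript length is argued against as the whole cause, since 56.4% of the genes stayed called with it removed, although the other calls ended. Depth is argued against, since 89.2% stayed called with all libraries thinned to the lowest total. A response that grows with dose above 20 µg/mL stays undecided for these genes as a set, since they went both ways. Their median signed change from 20 to 500 µg/mL of Sibjeondaebo-tang was -0.024 with quartiles of -0.078 and 0.031. The median size of their change against vehicle at 20 µg/mL of Palmul-tang was 0.222. Between 500 and 20 µg/mL 154 were called further in the same direction, 272 back and 3817 not. Growth was thus not called for most of them. Handling of the vehicle libraries apart from the others cannot be told apart from treatment, since all vehicle libraries carry a code set that no treated library has, although the titles of all 30 libraries name the same batch. Between the ethanol extracts and the formulas at 20 µg/mL, which carry different code sets, edgeR called 12 genes (796 at an unadjusted p under 0.05). The 796 lie under the share of 0.05 of all tested genes expected with no difference.

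Interferon genes such as MX1 were higher in Sibjeondaebo-tang at 100 µg/mL. Without replicate 2, the library with the highest total, 44.4% of the 18 called genes stayed called. Calls over all genes also went from 4389 to 3281 without it. The median of the interferon list was 0.363 ± 0.281 against vehicle (SD, n = 3). In Sibjeondaebo-tang it was 0.065 ± 0.073 at 20 µg/mL and 0.257 ± 0.009 at 500. In Palmul-tang it was 0.174 ± 0.126, 0.216 ± 0.03 and 0.239 ± 0.114 at 20, 100 and 500 µg/mL, so a rise was not particular to 1 group. The pattern at 100 µg/mL of Sibjeondaebo-tang thus leans on replicate 2, but fewer calls alone do not show how far. Growth with dose stays open: 1 interferon gene was called between 500 and 20 µg/mL and 0 between 100 and 20, but adjusted over the list alone there were 1 and 14. No biological explanation other than dose was tested.

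The cytokine genes, CXCL8 first, rose with dose in both formulas. RNA from macrophages or microglia is argued against: the summed CPM of their markers changed 0.971-fold from 20 to 500 µg/mL of Sibjeondaebo-tang and 0.99-fold in Palmul-tang, with C1QA and TYROBP at 0 in all libraries and most of the sum from PTPRC. A trend of GC content and length is argued against, since 100% of the 28 called genes stayed called with it removed. An ingredient that Samul-tang shares stays open, since the median of the list was 0.198 between its single libraries at 500 and 20 µg/mL, and 1 library per dose does not decide; it was also 0.238 in Poria Cocos and 0.128 in Atractylodis Rhizoma, and against vehicle it was 0.006 in Samul-tang and 1.097 in Palmul-tang at 500 µg/mL. A response to the extracts may be the source, as a hypothesis, and what in the extracts would cause it was not tested.

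Each comparison of 3 with 3 libraries was set beside all 10 splits of its 6 libraries, fitted alone, which are too few for a share under 0.05. Against vehicle the real split called 5755, 4649 and 5023 genes for Palmul-tang at 500, 100 and 20 µg/mL, and the highest other split called 0, 1 and 1. For Sibjeondaebo-tang they were 3552, 4713 and 4766, with 0, 1 and 1. For the means of Samul-tang, Poria Cocos and Atractylodis Rhizoma they were 4504, 4794 and 5110, with 1, 1 and 0. Between 500 and 20 µg/mL they were 1379 with 2 in Palmul-tang and 636 with 4 in Sibjeondaebo-tang, and between 100 and 20 µg/mL 30 with 5 in Sibjeondaebo-tang. In each of these 1 split, the real one, called as many genes. In Palmul-tang between 100 and 20 µg/mL 2 splits called as many as the real 29, the other 53. Between both formulas the real split called 0 genes at each dose, so 10 of 10 splits called as many, and the highest other called 10 at 500, 8 at 100 and 48 at 20 µg/mL. Splits that call more than the real one may come from a structure of the libraries other than the groups or from chance, and replicate numbers showed none (correlations from -0.053 to 0.092).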

How the results depend on the processing

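The test with a trend of GC content and transcript length removed was chosen only after the result was seen. The extracts with 1 library per dose have no replicate of a dose.

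Of the counts of called genes, all 16 were within 1.5 times under size factors of DESeq2, thinning and the replicate block. With no filter on low counts Sibjeondaebo-tang and Palmul-tang differed in 9, 7 and 3 genes at 500, 100 and 20 µg/mL, where 0 were called with it (863, 478 and 629 at an unadjusted p under 0.05 in edgeR), and 51 and 63 genes were called between 100 and 20 µg/mL of Palmul-tang and Sibjeondaebo-tang. The 863, 478 and 629 lie under the share of 0.05 of 17839 tested genes expected with no difference. DESeq2 called 2 genes at 500 µg/mL between both formulas. Fitted on the compared groups, Sibjeondaebo-tang at 500 against 20 µg/mL gave 636 genes, and with the GC trend removed its 100 against 20 gave 56. Leaving out 1 library gave 0 to 1 and 0 to 2 genes between both formulas at 500 and 100 µg/mL, and 15 to 24 and 17 to 40 between 100 and 20 µg/mL of Palmul-tang and Sibjeondaebo-tang. The cause was not tested.

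Of the lists called by camera, the number that held with an estimated correlation was 1, 1 and 0 for Palmul-tang at 500, 100 and 20 µg/mL against vehicle. It was 3, 2 and 2 for Sibjeondaebo-tang, and 0 at each dose between both. It was 2 for Palmul-tang at 500 against 20, 1 and 3 at 100 against 20, and 2, 5 and 6 for Samul-tang, Poria Cocos and Atractylodis Rhizoma. Fry was counted over all lists, whether camera called them or not. It called 20 and 14 for Palmul-tang at 500 and 20, 15 for Sibjeondaebo-tang at 20, 2, 0 and 0 between both, and 3 and 4 at 100 against 20. The agreement of both formulas depended on the cut on expression. Pearson's r was 0.084 over all 17839 genes, also with the replicate block, and 0.754 at a mean log2 CPM of at least 3.

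With the GC trend removed MMP14 went to 0 in Sibjeondaebo-tang at 100 µg/mL and to 0.016 in Poria Cocos, and HMOX1 to 0.116 in Poria Cocos. Without their 500 µg/mL library TIPARP and TXNIP went to -0.07 and -0.063 in Samul-tang, and HMOX1 to -0.109 in Atractylodis Rhizoma. Over all libraries left out they ran up to 0.278, 0.611 and 0.742. The cause was not tested. Of the pairs of a named gene and a comparison, called or not, 1112 stayed as they were and 104 lost a call with the GC trend removed, 1187 stayed and 19 lost a call in DESeq2, and over all fits with 1 library left out 6913 stayed and 426 lost a call.

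Replicate numbers did not pair the libraries: over 63 pairs with a shared number the correlation ran from -0.053 to 0.092. With the number as a block 1036 and 1258 genes were called between 500 and 20 µg/mL of Palmul-tang and Sibjeondaebo-tang and 35 and 53 between 100 and 20.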

Other observations

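The test of a hypothesis below was set before the values it measures were seen, while the hypothesis itself came from the fall of ID2 and ID4.

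ID2, ID4 and ID3 are targets of BMP signals, and lower BMP signalling may underlie their fall between 20 and 500 µg/mL. Of ID1, SMAD7, SMAD9, BAMBI and HEY1, 2 were called lower in both formulas: ID1 had -0.68 ± 0.069 in Palmul-tang (adjusted p = 3.53e-06) and -0.69 ± 0.068 in Sibjeondaebo-tang (adjusted p = 2.23e-06), and SMAD7 had -0.36 ± 0.081 (adjusted p = 0.00433) and -0.39 ± 0.078 (adjusted p = 0.000805). SMAD9 had -0.33 ± 0.166 (adjusted p = 0.325) and -0.63 ± 0.156 (adjusted p = 0.00913), and BAMBI and HEY1 were called in neither. At least 3 would have favoured the hypothesis and at most 1 would have argued against it, so it stays open.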
